A study of Portunus trituberculatus with 18 samples.

How the data were processed

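Total RNA of whole Portunus trituberculatus (swimming crab) larvae was labelled with Cy3 and hybridised to a custom one-colour Agilent array, with 1 array for each sample. The 18 samples are 3 biological replicates of 6 stages, the zoeae Z1, Z2, Z3 and Z4, the megalopa M and the first crab C. Per the labels, larvae were taken when most of the population had moulted to the stage, and were fed rotifers and a microalga in Z1 and Z2 and Artemia nauplii from Z3 on, so the change of food falls between Z2 and Z3.

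The deposited signals are intensity values, background-subtracted by the scanner software and not normalized between arrays. Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.7.1.1. The authors' normalized columns are log2 values that share the same distribution on all 18 arrays (median 4.13), which is the outcome of quantile normalization, so that quantile normalization here repeats them as a scaling, and the deposited value table of the series differs from them by at most 5.0e-09. The deposited flag of each probe and array is of another kind (other), a text that reads Detected, Not Detected or Compromised. The software and the rule behind the normalization and the flags are not stated.

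The deposited data hold 109589 probes, of which 56 are control probes and 109533 are crab probes. Of the latter, 19197 are named for an assembled contig, 87339 for a single sequencing read and 2997 for an expressed sequence tag. Gene Ontology (GO) terms stand beside 14975 crab probes and KEGG pathways beside 6446, 15810 with either, and 42 descriptions name a similar protein. Of the tag names, 0 matched the gene table of the reference. All counts are therefore counts of probes, not genes, and a probe is described by its contig or read name and its deposited terms. How far the terms were transferred from other species is not stated.

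Each signal was put on the log2 scale, and the 75th percentile of the array, taken over the 31355 probes detected on all 18 arrays, was subtracted. The 1936 probes flagged Compromised on at least 1 array were left out. A probe was tested if it was detected on all 3 arrays of at least 1 stage, which gave 58194 probes, 8878 of them with GO terms. Arrays give no counting depth, and the number of arrays limits the precision. Detected probes per array ran from 34.6% of the crab probes to 55.2%.

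The 5 comparisons set each stage against the stage before it, from 1 model with a mean per stage over all 18 arrays (R 4.3.3, limma 3.58.1, data.table version 1.17.8; 12 residual degrees of freedom and 2.89 prior degrees of freedom). Differences are the later stage minus the earlier one. A probe counts as changed, "rose" or "fell", at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 difference of at least 1. The moderated F test of limma over the 6 stages used the same thresholds on the range of the stage means. Errors after ± are standard errors of the model unless marked SD, with 3 arrays per stage.

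Before the data were examined, 19 topics were fixed as gene lists. These were cuticle proteins, chitin metabolism, ecdysteroid signalling, methyl farnesoate and juvenile hormone, neuropeptides and moulting hormones, digestive enzymes, muscle contraction, Hox and segment identity, vision, ion transport, innate immunity, haemocyanins and pigment binding, yolk and lipid transport, DNA replication and cell cycle, ribosomal proteins, oxidative phosphorylation, nervous system, heat shock and stress, and algal photosynthesis. They had been written as words of protein descriptions, and since few probes have one, GO terms and KEGG pathways were chosen to stand for each topic after the annotation was read and before any difference was computed. A probe may belong to several lists. Algal photosynthesis had 0 probes and the 18 other lists were tested with camera of limma at its preset correlation of 0.01 between probes, and again with an estimated correlation, with the Benjamini-Hochberg adjustment over the 90 tests of lists and comparisons. All 2041 GO terms and KEGG pathways with at least 10 tested probes were tested in the same way, with the adjustment over all terms and comparisons. The single terms named in the results were picked from these after their values were seen.

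The rule for named probes, fixed at the same point as the topics, took the 6 largest rises and the 6 largest falls of annotated probes in each comparison, among changed probes whose 3 values in one stage all lie on one side of the 3 values in the other and that were detected on all 3 arrays of the brighter stage, with 1 probe per set of terms, and the 2 largest changes of each list under the same conditions. Where the dimmer stage was not detected on any of its 3 arrays, the text gives a lower bound of the fold change in place of the fitted one. For the bound, each undetected value was raised to the lowest signal of any detected probe on its array. Where the dimmer stage was detected on only 1 or 2 arrays, the fitted difference is followed by the difference at the bounds, with undetected values raised in this way. Medians marked "at the bounds" treat the members of a list or term in this way, with 0 for members detected in neither stage.

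Alternatives were the authors' normalized values, quantile normalization, no filter on dim probes, only probes detected on all 18 arrays, no minimum difference, a trended and robust variance model, array weights, the replicate numbers as a block, only the arrays of the stages compared, and each array left out in turn. Further ones were chosen after the data were seen, namely the 75th percentile over all probes of an array, compromised probes kept, and Z2-peak probes (defined with the results) left out. Whether replicate numbers pair samples of successive stages was checked by the correlation across probes of the deviations from the stage means. It was 0.58, 0.39 and 0.60 for the replicates of Z2 and Z3. In each other comparison at least 1 number had 0.07 or less, so blocked counts are given for Z3 against Z2. The block was an effect of the replicate number common to all stages, not a pairing of Z2 and Z3 alone. The procedure was tested on simulated data with the Z4 levels and residual spreads of these probes and normal errors, with 50 probes changed in M at each size. It recovered 34%, 40%, 60% and 96% of log2 changes of 1.2, 1.5, 2 and 3 between Z4 and M, with 9 false calls among 58194 probes. Far fewer probes changed in the simulation than the 20300 called between Z4 and M in the data, which makes its adjusted threshold stricter. The recovery and the false calls are therefore those of the simulated setting and not of the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.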

Results

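The data are transcript levels in whole larvae of the swimming crab Portunus trituberculatus through 6 successive stages, with 3 arrays per stage. The series asks how expression differs between growth stages, and the comparisons follow development from each stage to the next. Detection was lowest on Z4 replicate 3, with 37851 crab probes (34.6%), and highest on C replicate 3, with 60452 (55.2%). The 12 zoeal arrays detected between 34.6% and 47.4% of the probes, and the 6 arrays of M and C between 51% and 55.2%.

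Of the 58194 probes tested, 38117 (65.5%) varied over the 6 stages in the moderated F test. The first principal component held 53.8% of the variance and set the 6 arrays of M and C, at 0.607 to 0.785, apart from the 12 zoeal arrays, at −0.673 to 0.036. Correlations across probes, where probes are not independent replicates, averaged 0.966 between M and C. Between M and the zoeae they averaged 0.829 for Z1, 0.878 for Z2, 0.902 for Z3 and 0.885 for Z4. Each Z2 array had its highest correlation with a Z3 array, at 0.978, 0.981 and 0.938 for replicates 1, 2 and 3, and replicates 1 and 2 correlated at 0.977 with each other. Z2 replicate 3 correlated less with the other arrays of Z2, at 0.893 and 0.918, and scored 0.822 on the second component, which held 14% of the variance.

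**Figure D1:**
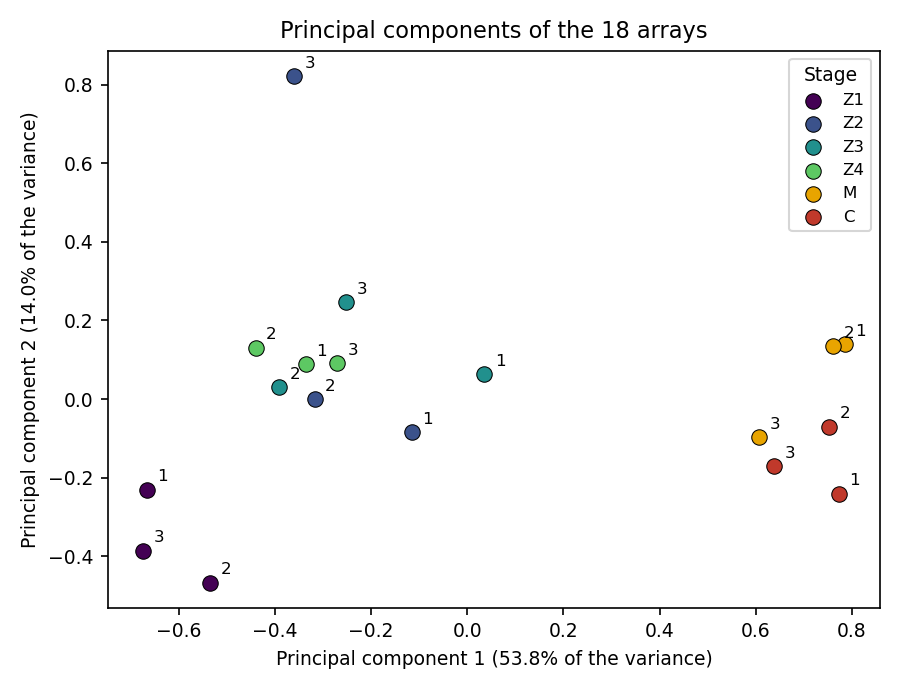
Scores of the 18 arrays on the first (53.8% of the variance) and second (14%) principal components of the log2 levels of 31355 probes detected on all arrays, coloured by stage and numbered by replicate. The arrays of M and C lie to the right of all zoeal arrays, and Z2 replicate 3 lies highest, at 0.822.

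The zoeal arrays also differed from those of M and C in measures other than crab transcripts. Compromised probes numbered 52 to 289 per zoeal array and 1 to 8 per array of M and C. Of 24 control probes detected on all arrays, 5 (20.8%) differed by more than 1 on the log2 scale between Z4 and M. The 24 ranged from −0.31 to 1.94 there, and 0 differed by more than 1 in each of the 4 other comparisons. They leave out the bright corner, which differed by 1.43 between Z4 and M. Their median was 0.46 for Z2 against Z1, −0.17 for Z3 against Z2, 0.31 for Z4 against Z3 and −0.07 for C against M. All 24 were higher in Z2 than in Z1, by 0.16 to 0.60. How far such shifts enter the list medians was not tested. The arrays thus differed in technical measures, and the labels give no slide or scan date. How far a technical difference enters the crab probes cannot be told apart from the stage in the comparison of M with Z4. The same holds for the first component, the F test and the levels of M and C relative to Z1.

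**Figure D2:**
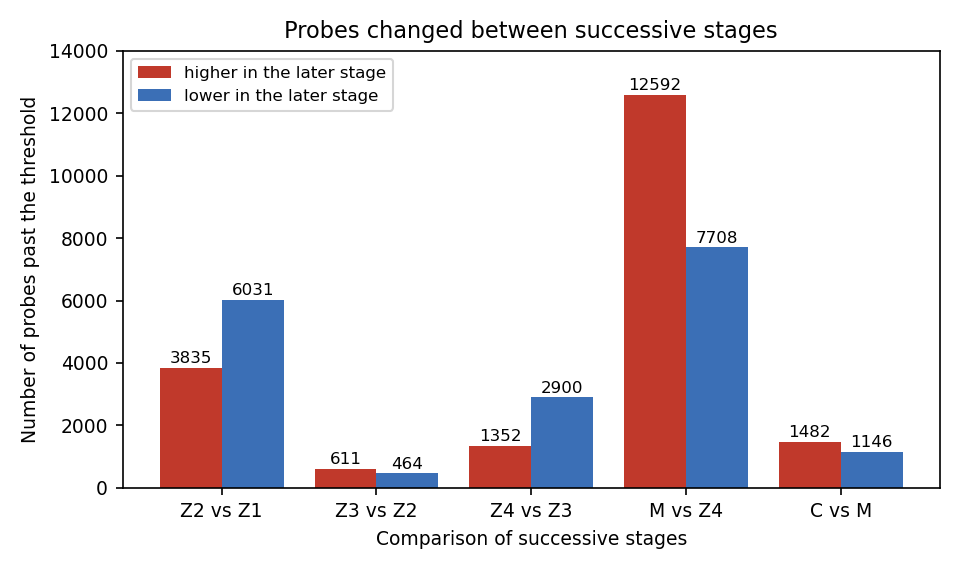
Number of tested probes (vertical axis) that were higher or lower in the later stage of each of the 5 comparisons, at an adjusted p below 0.05 and an absolute log2 difference of at least 1. M against Z4 had the most changes (12592 higher and 7708 lower) and Z3 against Z2 the fewest (611 higher and 464 lower).

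The comparison of Z2 with Z1 asks what changed after the first moult. In Z2, 18 of 47 probes for chitin metabolism and 8 of 19 for haemocyanins and pigment binding rose, and 12 of 15 for voltage-gated potassium channel activity fell. In the list of chitin metabolism, which covers the breakdown and renewal of the polysaccharide of the exoskeleton, 18 of 47 probes rose, 2 fell and 27 did not pass (21 and 2 adjusted over the list alone). Their median difference was 1.09 on the log2 scale (0.34 at the bounds) with adjusted p = 1.05e-07 (adjusted p = 0.673 with an estimated correlation). With only the probes detected on all 18 arrays the call ended, at 0.104 (range over 13 alternatives 4.33e-08 to 0.104). The chitinase probe IE2IK4G02HN7IG was at least 27.6-fold higher in Z2 (adjusted p 6.4e-07), and the hexosaminidase probe contig16354, whose enzyme class splits chitin fragments, rose by 6.51 ± 0.46. Among haemocyanins and pigment-binding proteins, 8 of 19 probes rose, 0 fell and 11 did not pass (9 and 0 adjusted over the list alone), with a median of 1.54 (0.95 at the bounds) and adjusted p = 3.96e-05 (adjusted p = 0.829 with an estimated correlation). The oxygen carrier probe contig16345 rose by 6.80 ± 1.35 (6.30 at the bounds).

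Digestive enzymes had 26 of 142 probes higher in Z2, 11 lower and 105 that did not pass (29 and 11 adjusted over the list alone), with a median of 0.45 (0 at the bounds) and adjusted p = 0.00408 (adjusted p = 0.874 with an estimated correlation). The serine endopeptidase probe contig21322 was at least 41.9-fold higher. This call rested on Z2 replicate 1, without which 14 probes were higher and adjusted p was 0.0946 (range over 13 alternatives 0.000932 to 0.202). The higher count was 16 without Z1 replicate 2 and 10 without Z1 replicate 3, and the lower count was 7 without Z1 replicate 3 or Z2 replicate 3. Cuticle proteins had 5 of 30 probes higher, 0 lower and 25 that did not pass (3 and 0 adjusted over the list alone), with a median of 0.58 (0.47 at the bounds) and adjusted p = 0.0258 (adjusted p = 0.874 with an estimated correlation). Without Z2 replicate 3 that p was 0.0635 (range over 13 alternatives 0.0198 to 0.446), and 3 probes were higher without any 1 of the 3 Z1 arrays, Z2 replicate 1 or Z2 replicate 2. Heat shock and stress had 10 of 110 probes higher, 5 lower and 95 that did not pass (9 and 5 adjusted over the list alone), with a median of 0.13 (0.07 at the bounds) and adjusted p = 0.0487 (adjusted p = 0.874 with an estimated correlation). This p was 0.0942 without Z1 replicate 1, 0.0647 without Z1 replicate 3, 0.391 without Z2 replicate 1, where the median was −0.02, and 0.0507 with the authors' values (range over 13 alternatives 0.00366 to 0.391).

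Ribosomal proteins and oxidative phosphorylation also had more probes higher in Z2, but most of these belonged to a group that peaked in Z2 alone. This group was defined after the values were seen as the probes at least 4 higher on the log2 scale in Z2 than in Z1 and at least 4 lower in Z3 than in Z2, both past the test. It holds 127 probes, all detected on each of the 3 Z2 arrays, as the filter required of the 107 that were detected on all 3 arrays of no other stage. Of the group 106 were not detected on any Z1 array and 66 were not detected on any Z3 array. Of 63 ribosomal probes, 15 rose, 1 fell and 47 did not pass (15 and 1 adjusted over the list alone), with a median of 0.27 (0.27 at the bounds) and adjusted p = 1.05e-07 (adjusted p = 0.829 with an estimated correlation), and 8 of the risers were Z2-peak probes. Without the Z2-peak probes 7 ribosomal probes were higher and adjusted p was 0.000232 (range over 13 other alternatives 6.65e-08 to 0.00286). Of 108 probes for oxidative phosphorylation, the mitochondrial production of ATP, 13 rose, 2 fell and 93 did not pass (13 and 2 adjusted over the list alone), with a median of 0.17 (0.11 at the bounds) and adjusted p = 0.00107 (adjusted p = 0.874 with an estimated correlation), and 11 of the risers were Z2-peak probes. Without them 2 were higher and adjusted p was 0.0851 (range over 13 other alternatives 0.000317 to 0.0346). The call of cuticle proteins, 1 of whose probes is in the group, also ended, with adjusted p = 0.0601 (range over 13 other alternatives 0.0198 to 0.446). Of the 6 largest annotated rises of the comparison 5 lie in the group, such as the cytochrome oxidase probe contig19348, which rose by 11.22 ± 2.12 (9.68 at the bounds), and the large-subunit ribosomal probe IE2IK4G01A41QY, which was at least 365-fold higher.

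**Figure D3:**
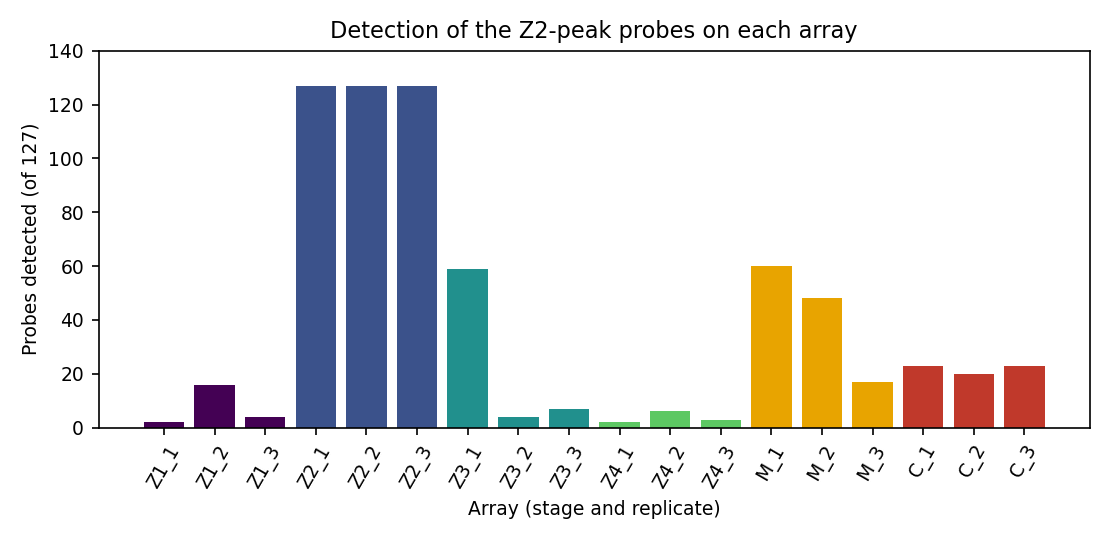
Number of the 127 Z2-peak probes detected (vertical axis) on each of the 18 arrays (horizontal axis), coloured by stage. All 127 were detected on each Z2 array, 59 on Z3 replicate 1, 60 on M replicate 1 and 48 on M replicate 2.

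Membrane channel probes were among those that fell in Z2. Of 15 probes annotated with voltage-gated potassium channel activity, which returns excited cells to rest, 12 fell and 0 rose (median −1.46, −1.21 at the bounds, adjusted p = 0.000138, and adjusted p = 1 with an estimated correlation). This count was 7 without Z1 replicate 2, 6 without Z1 replicate 3 and 7 without Z2 replicate 3, with the term still past its threshold each time. Of 45 probes for regulation of ion transmembrane transport, 25 fell and 0 rose (median −1.25, −0.83 at the bounds, adjusted p = 8.29e-05, and adjusted p = 1 with an estimated correlation). The list of the nervous system had 12 of 226 probes higher and 43 lower (adjusted p 0.0524), and muscle contraction 6 of 138 higher and 30 lower (adjusted p 0.0824), so neither list passed. The higher count for the muscle list was 10 without Z2 replicate 2. Single terms of these topics did pass downward in camera. Structural constituent of muscle had 18 of 56 probes lower and 1 higher (median −0.71, adjusted p = 0.00597, camera). Neurotransmitter secretion had 11 of 34 lower and 1 higher (median −0.76, adjusted p = 0.00072, camera). With an estimated correlation 0 terms passed in this comparison. Among single probes, the steroid receptor-type probe IE2IK4G01A31RJ was at least 2.14-fold lower in Z2 and the transcription regulator probe IE2IK4G01CFRQO fell by 4.41 ± 0.45 on the log2 scale (−4.02 at the bounds).

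The other lists did not pass between Z1 and Z2. Vision had 11 of 67 probes higher and 15 lower, DNA replication and cell cycle 22 of 241 higher and 23 lower, and innate immunity 12 of 156 higher and 7 lower. For immunity the higher count was 7 without Z1 replicate 1, 6 without Z1 replicate 3 and 7 without Z2 replicate 1, and the lower count 16 without Z2 replicate 1. Ion transport had 3 of 57 probes higher and 8 lower (4 lower without Z1 replicate 2 and 2 without Z2 replicate 3), and methyl farnesoate and juvenile hormone 5 of 17 higher and 1 lower (2 higher without Z2 replicate 1). Ecdysteroid signalling had 2 of 46 higher and 4 lower, Hox and segment identity 1 of 54 higher and 2 lower, neuropeptides and moulting hormones 2 of 34 higher and 2 lower, and yolk and lipid transport 1 of 15 higher and 1 lower. Single members with clear changes were the retinoid-binding vision probe contig11772, at least 18.8-fold higher, and the lipid transporter probe contig15096, annotated to haemolymph clotting, which rose by 3.36 ± 0.41. In all, 9866 of 58194 probes changed, 3835 higher and 6031 lower. The replicates of both stages did not overlap for 43.6% of the probes, against 10% by chance.

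The comparison of Z3 with Z2 spans the change from rotifers and microalga to Artemia nauplii. Of 58194 probes 1.8% changed, the lowest share of the 5 comparisons. The largest annotated rise was that of the glucuronosyltransferase probe contig20810, of an enzyme class that conjugates foreign compounds for excretion, which was at least 9.81-fold higher in Z3 (adjusted p 1e-06). The serine endopeptidase probe IE2IK4G01CMPXU was at least 3.29-fold higher. The carboxypeptidase probe IE2IK4G02IMTWT, of the digestive list, was at least 11.5-fold lower.

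Ribosomal proteins had 1 of 63 probes higher, 11 lower and 51 that did not pass (1 and 12 adjusted over the list alone), with a median of −0.09 (−0.09 at the bounds) and adjusted p = 1.45e-06 (adjusted p = 0.829 with an estimated correlation). Of the 11, 8 were Z2-peak probes, among them IE2IK4G01A41QY, which fell by 8.95 ± 1.40 (−7.48 at the bounds), and the small-subunit probe IE2IK4G02IQ0LK, which fell by 7.82 ± 1.06 (−6.33 at the bounds). Without the Z2-peak probes adjusted p was 0.0291, and with only the probes detected on all 18 arrays the call ended, at 0.0667 (range over 13 alternatives 2.27e-09 to 0.0667). Oxidative phosphorylation had 0 of 108 probes higher, 13 lower and 95 that did not pass (0 and 13 adjusted over the list alone), with a median of −0.04 (0 at the bounds) that was 0.05 with the authors' values, and adjusted p = 0.00324 (adjusted p = 0.874 with an estimated correlation). Of the 13, 11 were Z2-peak probes, such as the NADH dehydrogenase probe IE2IK4G01DU34E, which fell by 8.77 ± 1.53 (−7.27 at the bounds), and without these adjusted p was 0.534. The call also ended without Z2 replicate 1, at 0.164, and without Z3 replicate 2, at 0.254, each with a median of 0.08 (range over 13 alternatives 2.88e-06 to 0.428), and 8 probes were lower without Z3 replicate 3. None of the 16 other lists passed. Digestive enzymes had 5 of 142 probes higher and 3 lower (3 higher without Z2 replicate 3, Z3 replicate 2 or Z3 replicate 3), and innate immunity 3 of 156 higher and 2 lower.

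In all, 1075 probes changed between Z2 and Z3, 611 higher and 464 lower, and 15.5% did not overlap. Chance gives 10% only for exchangeable arrays, and the arrays of these stages with the same replicate number were correlated. Without Z3 replicate 3 there were 593 (299 higher, 294 lower), and without Z2 replicate 3 the higher count was 332. With the replicate number as a block in the model of all stages, 1029 changed, 578 higher and 451 lower. This block gives each replicate number the same effect in every stage. These counts therefore do not show the result of pairing the arrays of Z2 and Z3 alone. Without the Z2-peak probes 895 changed, 576 higher and 319 lower.

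The comparison of Z4 with Z3 covers the last zoeal moult. In Z4, 67 of 241 probes for DNA replication and the cell cycle, 12 of 30 for cuticle proteins and 7 of 19 for haemocyanins and pigment binding fell. Of 241 probes for DNA replication and the cell cycle, 2 rose, 67 fell and 172 did not pass (2 and 71 adjusted over the list alone). Their median was −0.44 (−0.21 at the bounds) with adjusted p = 1.31e-08 (adjusted p = 0.673 with an estimated correlation). Among the terms named here, picked after their values were seen, the fall was largest in the start of replication. Of 33 probes for DNA replication initiation 24 fell and 0 rose (median −2.12, −1.93 at the bounds, adjusted p = 6.04e-23, and adjusted p = 0.529 with an estimated correlation), as did 16 of 23 for the MCM complex, the helicase that opens the DNA (median −2.13, −1.93 at the bounds, adjusted p = 2.88e-16, and adjusted p = 0.468 with an estimated correlation). Of 30 probes for mismatch repair 18 fell and 0 rose (median −1.39, −1.12 at the bounds, adjusted p = 5.97e-13, and adjusted p = 1 with an estimated correlation). The helicase probe IE2IK4G02GFPDN was at least 4.41-fold lower in Z4 and IE2IK4G02GUTJK fell by 3.52 ± 0.48 (−3.12 at the bounds).

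Of 30 probes for cuticle proteins 12 fell, 1 rose and 17 did not pass (14 and 1 adjusted over the list alone), with a median of −1.56 (−1.18 at the bounds) and adjusted p = 1.45e-06 (adjusted p = 0.673 with an estimated correlation). Probe IE2IK4G02I31RD fell by 7.70 ± 1.45 (−6.93 at the bounds) and IE2IK4G02HEODJ was at least 2.88-fold lower, whereas contig24192, annotated to the chitin-based larval cuticle, rose by 3.28 ± 0.73 (2.13 at the bounds). Haemocyanins and pigment binding had 0 of 19 probes higher, 7 lower and 12 that did not pass (0 and 10 adjusted over the list alone), with a median of −1.21 (−0.64 at the bounds) and adjusted p = 0.00214 (adjusted p = 0.874 with an estimated correlation). There were 4 lower without Z3 replicate 1 or Z4 replicate 1, and the list median log2 difference, haemocyanins and pigment binding, Z4 vs Z3, was −1.90 without Z3 replicate 2 and −2.01 without Z3 replicate 3. The oxygen carrier probe contig16345, higher in Z2 than in Z1, fell by 6.25 ± 1.35 (−5.14 at the bounds).

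Single digestive peptidases fell steeply in Z4 while the list as a whole did not pass (adjusted p 0.706), with 8 of 142 probes higher and 17 lower. Higher counts were 5 without Z3 replicate 2, 4 without Z3 replicate 3 and 5 without Z4 replicate 1, and the lower count was 11 without Z3 replicate 1. The serine endopeptidase probes contig22757 fell by 8.06 ± 1.26 (−7.75 at the bounds) and contig21407 fell by 7.81 ± 1.17 (−7.46 at the bounds), and the metalloendopeptidase probe contig21445 was at least 284-fold lower. Chitin metabolism had 1 of 47 probes higher and 10 lower (adjusted p 0.0759), with 6 lower without Z4 replicate 2. Probe contig19499, annotated to juvenile hormone biosynthesis, fell by 2.77 ± 0.29. The acylphosphatase probe contig16460 rose by 2.94 ± 0.15 and contig20810, the glucuronosyltransferase, by 2.90 ± 0.39. In all, 4252 probes changed, 1352 higher and 2900 lower (31.8% higher), and 32.4% did not overlap, against 10% by chance. With the 75th percentile over all probes, which moves the median difference by 0.11, 1938 were higher and 2434 lower (44.3% higher).

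The comparison of M with Z4 covers the metamorphosis to the megalopa and had the most changes. In M, 68 of 142 probes for digestive enzymes, 13 of 19 for haemocyanins and pigment binding, 24 of 47 for chitin metabolism and 10 of 17 for methyl farnesoate and juvenile hormone rose. Of 142 probes for digestive enzymes 68 rose, 5 fell and 69 did not pass (68 and 5 adjusted over the list alone), with a median of 1.16 (0.65 at the bounds) and adjusted p = 6.65e-06 (adjusted p = 0.874 with an estimated correlation). The serine endopeptidase probes contig21322 and contig06320 led the list, the first 13.04 ± 1.31 higher (11.90 at the bounds) and the second at least 1260-fold higher in M. Among other annotated probes, the lipase probe contig19104 was at least 1300-fold higher, the metalloendopeptidase probe contig21445 at least 5360-fold higher and the carboxypeptidase probe contig06079 rose by 11.59 ± 1.28 (11.45 at the bounds). Of 19 probes for haemocyanins and pigment binding, 13 rose, 0 fell and 6 did not pass (13 and 0 adjusted over the list alone), with a median of 3.19 (1.11 at the bounds) and adjusted p = 6.82e-05 (adjusted p = 0.829 with an estimated correlation). The oxygen carrier probe contig16345 rose by 10.67 ± 1.35 (9.56 at the bounds).

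Chitin metabolism had 24 of 47 probes higher in M, 1 lower and 22 that did not pass (24 and 1 adjusted over the list alone), with a median of 1.33 (0.83 at the bounds) and adjusted p = 0.0027 (adjusted p = 0.874 with an estimated correlation). With only the probes detected on all 18 arrays the call ended, at 0.369 (range over 13 alternatives 0.000154 to 0.369). The chitinase probe contig19061 rose by 11.17 ± 1.49 (9.93 at the bounds) and the chitin-binding probe contig22479 was at least 157-fold higher. Of 17 probes for methyl farnesoate and juvenile hormone, related hormones of crustaceans and insects, 10 rose, 0 fell and 7 did not pass (10 and 0 adjusted over the list alone), with a median of 1.31 (1.07 at the bounds) and adjusted p = 0.00298 (adjusted p = 0.874 with an estimated correlation). Its largest changes were in the haem-binding probes IE2IK4G02HI3HE, at least 14.0-fold higher, and IE2IK4G01AU1I1, at least 6.05-fold higher and also annotated to ecdysone biosynthesis. Ribosomal proteins had 18 of 63 probes higher, 5 lower and 40 that did not pass (18 and 5 adjusted over the list alone), with a median of 0.68 (0.36 at the bounds). Oxidative phosphorylation had 17 of 108 higher, 6 lower and 85 that did not pass (17 and 6 adjusted over the list alone), with a median of 0.54 (0.38 at the bounds). Both had adjusted p = 0.0111 (adjusted p = 0.874 with an estimated correlation). With the authors' values these were 0.321 (range over 13 alternatives 0.000169 to 0.321) and 0.0562 (range 0.000593 to 0.0562), so both calls ended.

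Several lists had many changed probes without passing as lists. Muscle contraction had 40 of 138 probes higher and 12 lower (adjusted p 0.0955), with the motor protein probe contig00057 up by 4.71 ± 0.47 (4.37 at the bounds). Vision had 27 of 67 higher and 11 lower (adjusted p 0.176), and within it the photoreceptor-type receptor probe contig18523 fell by 4.90 ± 0.44 while the G protein probe IE2IK4G02JR6I9 was at least 8.77-fold higher. The nervous system had 60 of 226 higher and 26 lower, innate immunity 34 of 156 higher and 13 lower, and Hox and segment identity 7 of 54 higher and 8 lower. DNA replication and cell cycle had 42 of 241 higher and 11 lower (7 lower without Z4 replicate 1). The peroxisomal probe contig20329, annotated as alkylglycerone-phosphate synthase of ether lipid synthesis, fell by 6.49 ± 0.65, and the voltage-gated chloride channel probe IE2IK4G02IFUCJ by 4.75 ± 0.60. In all, 20300 probes changed, 12592 higher and 7708 lower, and 64.3% did not overlap, against 10% by chance. Of the higher ones 5352 were not detected on any Z4 array, and among the probes detected on all 18 arrays 4430 were higher and 4750 lower. Without a filter on dim probes 46.8% of the calls were higher, against 62% with it. In this comparison 20.8% of the control probes differed by more than 1.

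The comparison of C with M follows the moult to the first crab. In C, 20 of 138 probes for muscle contraction, 40 of 241 for DNA replication and cell cycle and 8 of 30 for cuticle proteins rose, and 8 of 67 for vision and 9 of 142 for digestive enzymes fell, while most members of these lists did not pass. Of 138 probes for muscle contraction 20 rose, 1 fell and 117 did not pass (23 and 2 adjusted over the list alone), with a median of 0.46 (0.44 at the bounds) and adjusted p = 5.27e-08 (adjusted p = 0.673 with an estimated correlation). The higher count was 5 without M replicate 1, 10 without M replicate 2, 7 without C replicate 1 and 8 without C replicate 3. The tropomyosin-binding probe contig06067 was at least 1.14-fold higher. Of 241 probes for DNA replication and cell cycle 40 rose, 3 fell and 198 did not pass (44 and 3 adjusted over the list alone), with a median of 0.27 (0.27 at the bounds) and adjusted p = 3.92e-06 (adjusted p = 0.829 with an estimated correlation). The higher count was 25 without M replicate 1, 22 without M replicate 2, 18 without C replicate 1 and 22 without C replicate 3. Of 33 probes for DNA replication initiation 21 rose and 0 fell (median 1.28, 1.22 at the bounds, adjusted p = 1.01e-14, and adjusted p = 1 with an estimated correlation), and 12 rose without C replicate 1. The cytokinesis kinase probe contig12199 fell by 3.67 ± 0.55.

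Cuticle proteins had 8 of 30 probes higher in C, 0 lower and 22 that did not pass (12 and 0 adjusted over the list alone), with a median of 0.55 (0.55 at the bounds) and adjusted p = 0.000152 (adjusted p = 0.673 with an estimated correlation). Probe IE2IK4G02I31RD, which had fallen in Z4, rose by 8.24 ± 1.45. There were 3 higher without M replicate 1 or C replicate 3 and 5 without M replicate 3 or C replicate 1. Vision had 0 of 67 probes higher, 8 lower and 59 that did not pass (0 and 9 adjusted over the list alone), with a median of −0.12 (−0.11 at the bounds) and adjusted p = 0.00164 (adjusted p = 0.829 with an estimated correlation). Both largest falls were of photoreceptor-type receptor probes, of which contig18523 fell by 5.41 ± 0.44 and IE2IK4G01BQHQK fell by 4.88 ± 0.41 (−4.73 at the bounds). Digestive enzymes had 0 of 142 higher, 9 lower and 133 that did not pass (0 and 9 adjusted over the list alone), with a median of −0.18 (−0.16 at the bounds) and adjusted p = 0.0027 (adjusted p = 0.874 with an estimated correlation). There were 16 lower without C replicate 2. The serine endopeptidase probe contig11945 fell by 5.66 ± 0.46.

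Haemocyanins and pigment binding had 3 of 19 probes higher in C, 1 lower and 15 that did not pass (3 and 1 adjusted over the list alone), with a median of 1.17 (1.17 at the bounds) and adjusted p = 0.00235 (adjusted p = 0.874 with an estimated correlation). The list median log2 difference, haemocyanins and pigment binding, C vs M, was 0.41 without C replicate 1. The oxygen carrier probe contig12158 rose by 10.83 ± 0.64. Oxidative phosphorylation had 2 of 108 higher, 4 lower and 102 that did not pass (2 and 4 adjusted over the list alone), with a median of −0.15 (−0.13 at the bounds) and adjusted p = 0.0085 (adjusted p = 0.874 with an estimated correlation). That call ended without M replicate 1, at 0.111, and without C replicate 3, at 0.189 (range over 13 alternatives 0.00146 to 0.189). Chitin metabolism did not pass (adjusted p 0.128) with 7 of 47 higher and 0 lower, and 2, 4 and 3 higher without M replicate 1, C replicate 1 and C replicate 3. Its chitinase probe contig21996 rose by 4.28 ± 0.71. The tRNA methylation probe contig22340 was at least 729-fold higher, the calcium-activated chloride channel probe contig22088 rose by 3.48 ± 0.50, and the mannose-binding immune probe IE2IK4G02HF6CG fell by 6.52 ± 0.70 (−6.34 at the bounds). In all, 2628 probes changed, 1482 higher and 1146 lower, and 26.8% did not overlap, against 10% by chance. The total was 1689 without M replicate 1 (933 higher, 756 lower), 1643 without M replicate 2 (916 and 727) and 1603 without C replicate 1 (898 and 705), and 942 were higher without C replicate 3.

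**Figure D4:**
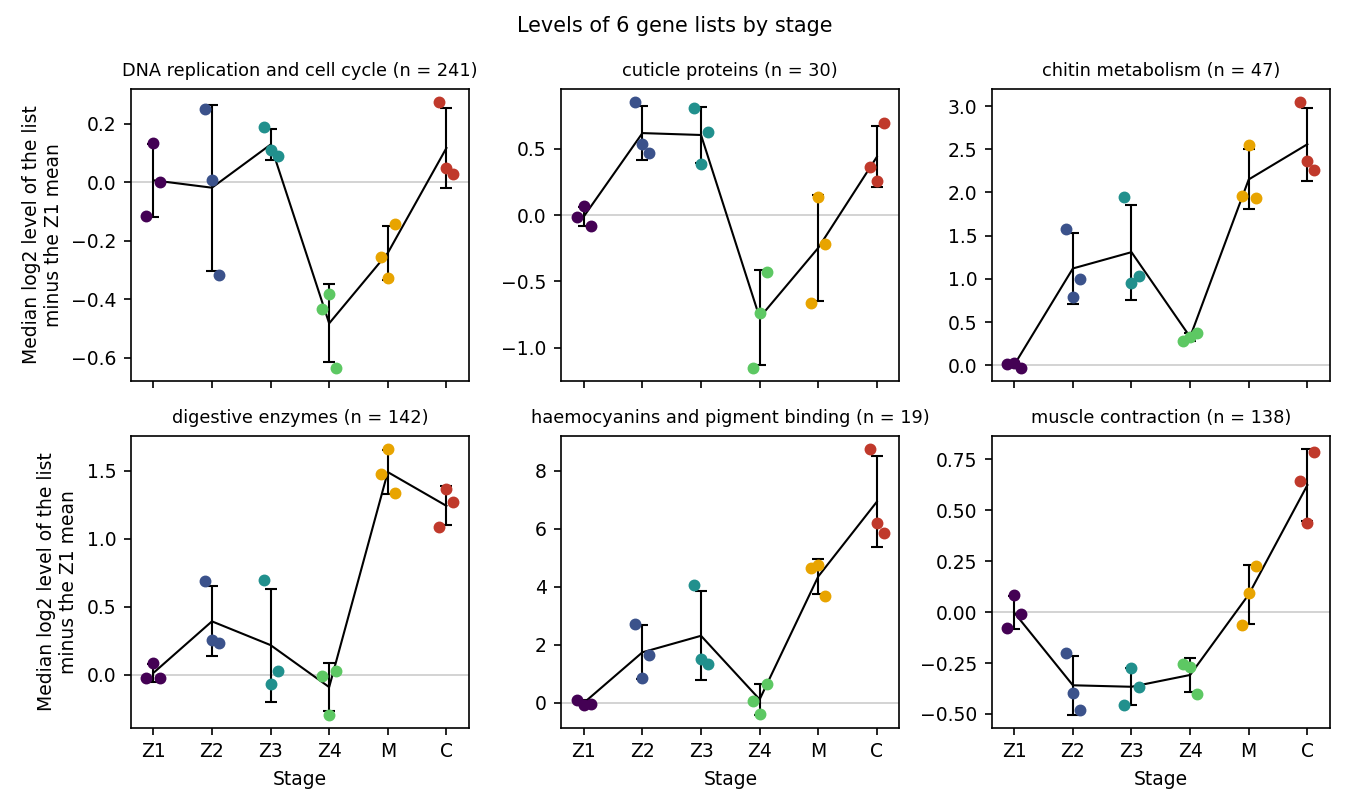
Level of 6 gene lists on each array, as the median over the list of the log2 level minus the Z1 mean of each probe (vertical axes, log2, own scale per panel), by stage (horizontal axes). Points are the 3 arrays of a stage, lines join stage means and bars are ± 1 SD; DNA replication is at −0.48 ± 0.13 in Z4 and 0.12 ± 0.14 in C.

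Of the 90 tests of lists, 25 passed with the preset correlation and 0 with the estimated one in camera of limma, where 5 had an unadjusted p below 0.05. In those 25 the median, mean and test had the same sign, and in 16 of the 65 others they did not.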

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

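The tests of this part were chosen after the result they examine was seen, apart from the repeats fixed beforehand (only probes detected on all 18 arrays, no filter on dim probes, the authors' values, each array left out). Control probes are outside the tests of crab probes. Of 13 probes of the ETG series 9 were detected on 0 arrays, whereas ETG02_36680 and ETG09_48764 were each detected on 18 of 18.

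With 3 arrays against 3 there are 10 splits, so the share of splits as large can never be below 0.1, and in each comparison the real one was the 1 of 10 with as many calls. For Z2 against Z1 the real split gave 9866 probes and the highest other split 2. For Z3 against Z2 these were 1075 and 44, and among the 4 splits that part all 3 replicate pairs, as the real one does, the highest other gave 0. They were 4252 and 2 for Z4 against Z3, 20300 and 2 for M against Z4, and 2628 and 0 for C against M. For the F test over the 6 stages, 1 of 100 groupings of the 18 arrays gave as many probes as the real 38117, the real one itself, and the highest other gave 22224. This argues against chance there, although the share cannot be below 1 of 100. It does not bear on the technical difference between zoeal arrays and those of M and C.

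The first pattern is the size of the change from Z4 to M. Dim probes near the detection floor are argued against as the whole cause of the count, since among probes detected on all 18 arrays 29.3% changed, against at most 15.4% in the 4 other comparisons. The excess of higher calls, 62%, was absent among these probes (48.3%) and without the filter on dim probes (46.8%), and a part of the filter in it cannot be told apart, because the lowest percentile of signals was 2.56 to 3 on the M arrays and 4 to 6.71 on those of Z4, so that dim probes can read lower in M. How far a technical difference between the arrays of Z4 and M enters the count cannot be told apart from the stage either. No label gives a slide or scan date, and 20.8% of the control probes moved by more than 1, up to 1.94. Of these movers 2 are the ETG probes named above, ETG09_48764 at 1.94 and ETG02_36680 at 1.75. The largest other mover was (+)E1A_r60_n9, at 1.89. What the ETG probes bind was not tested. Of the 20300 calls 7368 exceed 1.94. Metamorphosis itself stays open as an untested biological explanation.

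The second pattern is the 127 probes that peak in Z2. Contamination of a single Z2 library is argued against for these 127 probes, whose median lay 6.44, 7.25 and 5.98 above Z1 on the 3 Z2 arrays. It would leave the other Z2 arrays near Z1, whereas all 127 lay above every Z1 array on each Z2 array. Only probes with such levels could enter a group chosen on a high mean and a small p, so this covers the members alone. Of 699 probes chosen on Z2 replicate 1 and detected on it, 112 of them in the group, 21.9% were detected on Z2 replicate 2. Over such choices on each Z2 array, the share detected on another ran from 21.9% to 42.6%. Most probes so chosen lie outside the group, so this check does not decide the question for the 127. RNA of another organism in these samples is a candidate explanation: 27.9% of the annotated ones (19 of 68) belong to the ribosomal or oxidative phosphorylation lists, against 1.6% of the other annotated probes, but the group was defined after these members had been seen, so the share is no independent evidence. Transcripts of the crab itself switched on in Z2 cannot be told apart, since no table compares the probe sequences with other genomes, and 109 of the 152 other probes of these lists were detected on all 18 arrays. Of the 127 probes, 59 were detected on Z3 replicate 1, 60 on M replicate 1 and 48 on M replicate 2. The 19 brightest had a mean log2 level minus Z2 of −4.81 (SD 0.61 over probes) on Z3 replicate 1. It was −8.2 (SD 2.59) on Z1 replicate 2, −6.7 (SD 2.32) on M replicate 1 and −7.76 (SD 2.27) on M replicate 2. The narrow spread rests on 1 array and the brightest probes, so it does not decide between another organism and the crab. Food as the source was not tested. Z1 had the same food, and its replicates 1, 2 and 3 detected 2, 16 and 4 of the 127 probes. The time on this food was not compared between Z1 and Z2.

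The third pattern is the fall of DNA replication and cell cycle probes in Z4. The scaling is argued against, as at least 65 of 241 members were lower under each of 2 other scalings, the authors' values and the 75th percentile over all probes, against 67. A single array is argued against too, since at least 57 were lower without any 1 of the 6 arrays. Loss of dim probes below detection does not account for 26 of the 113 members detected on all 18 arrays, which fell while 2 rose, but for the list as a whole it cannot be told apart: these 113 had a median of −0.17, against 0.03 for the other such probes, with permutation p = 2e-04 over 10000 draws of probes taken as independent and p = 0.207 in camera of limma with an estimated correlation. The stage itself, or the point of the moult cycle at which larvae of a stage were taken, may underlie the fall, and no label separates these.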

How the results depend on the processing

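The alternatives with the 75th percentile over all probes, with compromised probes kept and without the Z2-peak probes were chosen after the data were seen. Counts of changed probes stayed within 1.5 times the reported ones under the authors' values, quantile normalization, the 75th percentile over all probes, compromised probes kept, the trended and robust model and the replicate block, and without the Z2-peak probes for Z2 against Z1 and Z3 against Z2. Without a filter on dim probes 15466 were lower in M than in Z4 and 65580 varied over the stages, as more probes were tested. With only probes detected on all 18 arrays, fewer probes tested, the changed, higher and lower counts were 4824, 2076 and 2748 for Z2 against Z1, 379, 222 and 157 for Z3 against Z2, 1969, 713 and 1256 for Z4 against Z3, 9180, 4430 and 4750 for M against Z4, and 1342, 701 and 641 for C against M, and 19595 varied over the stages. With no minimum difference, a looser call, they were 16013, 5998 and 10015 for Z2 against Z1, with 2186 higher in Z4 than in Z3 and 11869 lower in M than in Z4. With array weights they were 7069, 2676 and 4393 for Z4 against Z3 and 6288, 3321 and 2967 for C against M, and the cause was not tested. With only the arrays of the stages compared, fewer samples, they were 6021, 2212 and 3809 for Z2 against Z1 and 203, 81 and 122 for Z3 against Z2, and C against M had 1689 changed and 659 lower. Leaving out 1 array of a comparison at a time gave 593 to 1403 changed, 299 to 876 higher and 294 to 595 lower for Z3 against Z2, and 1603 to 3219 changed, 898 to 1774 higher and 705 to 1476 lower for C against M. The ranges were 7293 to 12088 changed for Z2 against Z1, 2911 to 4612 for Z4 against Z3, 17598 to 21471 for M against Z4 and 36204 to 39635 varying over the stages. List calls that ended with only probes detected on all 18 arrays were those of chitin metabolism in Z2 and M, cuticle proteins and digestive enzymes in Z2, ribosomal proteins and oxidative phosphorylation in Z3 and oxidative phosphorylation in C. Without the filter the calls of cuticle proteins and heat shock in Z2 and oxidative phosphorylation in Z3 ended, and keeping compromised probes ended that of heat shock in Z2. Over all alternatives the named differences kept direction and side of the threshold 2719 times, lost the call 192 times and gained one 3 times, and 0 reversed. Not run were a background correction on separate background signals, which are not used here, a mean over probes of 1 gene, since no identifier groups the probes, and a slide or scan date block, since the labels give none. Signal over background limits the dim probes. Changes of 2 or less on the log2 scale were recovered in at most 60% of simulated cases, in a setting with far fewer changed probes than M against Z4.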

Other observations

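The test of probes shared between Z4 and C was fixed before its result was seen; the tests of other shared sets and of shared sets without 1 array were chosen after, and the terms below were picked from all 2041 after their values were seen. Of 32 probes annotated with aromatase activity, a term carried by cytochrome P450 enzymes, 14 rose and 0 fell in Z2 (median 1.17, 0.59 at the bounds, adjusted p = 3.84e-06, and adjusted p = 1 with an estimated correlation), and 25 rose and 1 fell in M (median 1.85, 1.42 at the bounds, adjusted p = 8.29e-05). Between these, 10 fell and 0 rose in Z4 (median −1.11, 0 at the bounds, −0.50 without Z3 replicate 1, adjusted p = 0.000109, and adjusted p = 1 with an estimated correlation). The level of the term minus Z1 was 1.24 ± 0.65 (SD, n = 3 arrays) in Z2, 0.85 ± 0.83 in Z3, −0.11 ± 0.25 in Z4, 1.89 ± 0.05 in M and 2.54 ± 0.39 in C. The term also passed downward in Z3, with 0 probes past the test (median −0.54, −0.60 at the bounds, adjusted p = 0.00282), and upward in C, with 4 higher, or 2 without C replicate 1 or C replicate 2 (median 0.64, 0.64 at the bounds, adjusted p = 0.00789), each with adjusted p = 1 with an estimated correlation. The median in Z3 was −0.29 without Z2 replicate 1 or Z3 replicate 2, and −1.15 with 3 lower without Z3 replicate 1. Adjusted within the comparison by limma, p in Z3 was 0.219 without Z2 replicate 1, 0.445 without Z3 replicate 2 and 0.092 without Z3 replicate 3. In C this p was 0.0825 without C replicate 2 and 0.0843 without M replicate 3, and each of these omissions ended the call. In M the pathway of pentose and glucuronate interconversions, which includes glucuronosyltransferases, had 26 of 33 probes higher and 1 lower (median 2.20, 1.27 at the bounds, adjusted p = 9.41e-06), and retinol metabolism 21 of 28 higher and 0 lower (median 2.13, 1.1 at the bounds, adjusted p = 3.79e-05). In Z4 retinol metabolism had 6 of 28 probes lower and 0 higher (median −1.17, −0.26 at the bounds, −0.52 without Z3 replicate 1, adjusted p = 0.000441, and adjusted p = 1 with an estimated correlation). Pentose and glucuronate interconversions had 4 of 33 lower in Z4 (2 without Z3 replicate 1 or Z4 replicate 1, 7 without Z3 replicate 2 or Z4 replicate 2), with adjusted p = 0.00388 (adjusted p = 1 with an estimated correlation), a call that ended without Z3 replicate 1 (p = 0.117, limma, adjusted within the comparison). Of 135 probes of the lysosome, the compartment that degrades taken-up material, 71 rose and 3 fell in M (median 1.16, 0.78 at the bounds, adjusted p = 4.19e-06). Each of these 4 terms had adjusted p = 1 in M with an estimated correlation. Presynaptic active zone probes went the other way in M, with 8 of 24 lower and 2 higher, or 1 higher without M replicate 1 or Z4 replicate 3 (median −0.75, −0.74 at the bounds, adjusted p = 0.0278, and adjusted p = 1 with an estimated correlation).

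Of 71 probes for protein folding 24 rose and 0 fell in Z2 (median 0.75, 0.48 at the bounds, adjusted p = 2.99e-08, and adjusted p = 1 with an estimated correlation), while 3 were lower without Z2 replicate 1 and 2 without Z2 replicate 2. Of 13 probes of the chaperonin-containing T-complex, which folds actin and tubulin, 8 rose and 0 fell (median 1.05, 1.02 at the bounds, adjusted p = 3.01e-06, and adjusted p = 1 with an estimated correlation). There were 5 higher without Z1 replicate 1 or Z1 replicate 3 and 4 without Z2 replicate 1. Proteasome probes rose too, 11 of 42 with 1 lower (median 0.77, 0.72 at the bounds, adjusted p = 1.78e-06, and adjusted p = 1 with an estimated correlation), with 6 higher without Z1 replicate 3, 7 without Z2 replicate 1 and 19 without Z2 replicate 3. The proteasome level minus Z1 was 0.79 ± 0.36 (SD, n = 3 arrays) in Z2, 1.2 ± 0.23 in Z3, 1.57 ± 0.09 in Z4, 1.72 ± 0.08 in M and 1.36 ± 0.2 in C. The term also passed in Z3 (median 0.42, 0.38 at the bounds, adjusted p = 0.00435) and Z4 (median 0.37, 0.32 at the bounds, adjusted p = 0.00146), and downward in C (median −0.27, −0.26 at the bounds, adjusted p = 0.00779), each with adjusted p = 1 with an estimated correlation. Adjusted within the comparison by limma, p in Z3 was 0.292 without Z2 replicate 2, 0.0515 without Z2 replicate 3, 0.167 without Z3 replicate 1 and 0.092 without Z3 replicate 3, p in Z4 was 0.063 without Z3 replicate 2, and p in C was 0.226 without C replicate 3, which ended these calls. The nuclear receptor probe IE2IK4G02IIUN5, of the ecdysteroid list, was at least 2.72-fold lower in Z2 and rose by 1.57 ± 0.32 in Z4.

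Probes detected on all 3 arrays of 1 stage and on 0 of the 15 other arrays numbered 179 in Z1, 64 in Z2, 13 in Z3, 7 in Z4, 100 in M and 299 in C. Of these, 61 in Z2 and 51 in C lay at least 3 on the log2 scale above the mean of every other stage, against 9 in Z1, 3 in Z3, 2 in Z4 and 2 in M. Arrays of M and C detected 51% to 55.2% of the probes and zoeal arrays 34.6% to 47.4%. The counts of the stages therefore depend on detection too. How many of those in Z2 are Z2-peak probes is not given here.

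One hypothesis is that replication probes lost in Z4 are those regained in C. The 2 comparisons share no array, but both use the spread of each probe estimated over all 18 arrays. A probe with a small spread is called more readily in both, so the numbers for independent sets are only a rough reference. Of the 241 members of the list 67 fell in Z4 and 40 rose in C, and 33 did both, against 11.1 for independent sets (Fisher's exact test, one-sided, p = 1.66e-15, which treats probes as independent). Without C replicate 1 there were 18, against 5 for independent sets, without C replicate 3 21, against 6.1, and without M replicate 2 22, against 6.2. The overlap went beyond the list, with 321 of all tested probes falling in Z4 and rising in C, against 73.9 for independent sets, or 178 without M replicate 1, 190 without M replicate 2, 159 without C replicate 1 and 181 without C replicate 3. A shared set of transcripts that is low from Z4 to M could give this overlap, and so could high variance of the probes in both sets. High variance would also raise the number that fell in both comparisons, which was 64 against 57.1 for independent sets (0 against 0.8 in the list). This argues against high variance as the whole cause. The limit is that 937 of the 2900 probes that fell in Z4 were not detected on any Z4 array, which leaves little room for a second fall. For cuticle proteins 7 probes did both, against 3.2 (one-sided Fisher's exact test, p = 0.00252), but 3 without M replicate 1 (p = 0.0704, exact) or C replicate 3 (p = 0.0542, exact) and 4 without Z3 replicate 1 or M replicate 3 (p = 0.0294 and 0.0681, exact). For muscle contraction 1 did both, against 0.6 (p = 0.469, exact), and 0 without M replicate 1, M replicate 2, C replicate 1 or C replicate 3.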
